A study of Mus musculus with 21 samples.

How the data were processed

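The samples are cells of mouse (CD1) back skin at embryonic day 15.0, the age at which the first hair follicles form and dermal fibroblasts gather into dermal condensates below the epidermis. The labels list 12 bulk RNA samples and 9 single-cell libraries. The 12 bulk samples were not analysed here. Each single-cell library is a plate of wells into which live cells were sorted by flow cytometry, and per the labels' protocols it was made by SORT-seq, an automated form of CEL-Seq2 that tags each RNA molecule with a random barcode (unique molecular identifier, UMI), and sequenced on a NextSeq500. Per the submitters' processing notes, the genome build was mm10 and the tools were TopHat2 2.0.3, Bowtie2, Cufflinks 2.1.1 and BWA 0.6.2-r126, with no role given for any of them.

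A sole deposited table held all 9 libraries, with 20370 rows (86 spike-in RNAs and 20284 genes, among them a row named eGFP, a fluorescent protein) and 1967 wells. The prefix of each well name gave its population: Fb (fibroblast, 1371 wells), DC0 (149), DC1 (152), DC2 (151) or ERCC (144 wells named for spike-ins). The labels do not define DC0. Titles of the bulk samples name a pre-DC group beside DC1 and DC2, and whether it matches DC0 is not stated. The labels also do not say whether the prefix came from the sort or from clustering the cells. In library 8, DC0 filled wells 123 to 246 without a gap and DC2 lay in wells 247 to 376. In library 9, DC1 filled wells 1 to 122. Such blocks argue against names from clusters in these libraries. In libraries 1 to 7 no population filled a block of wells, and there the origin stays open. Wells with as few as 25 UMIs (Fb, library 1) and 68 UMIs (DC1, library 4) were named there too. The series text says that clusters of cells were used to find stages of condensate development. If the prefixes in libraries 1 to 7 follow those clusters, the genes that separate the populations were partly selected by them.

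The values the authors deposited are expected counts: for each gene and well, the number of distinct UMIs adjusted for chance collisions in a space of 4096 UMIs. This was read from the values, since 0 of 7480233 values above 0 differed by more than 0.005 from that formula applied to a whole number. The deposited values were not scaled to a common total per well. They were rounded to whole numbers, which changed 13.5% of the values above 0, and are called UMIs in the text. Their sum was 101% of the UMIs recovered by inverting the formula. The design had assumed whole counts.

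UMIs were summed over the wells of a population within a library. Genes were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM scaling, filterByExpr), with the library as a block and Benjamini-Hochberg adjustment at 0.05. R was 4.3.3, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, leidenalg 0.10.2 and igraph 0.11.9. Unless said otherwise, a level is in CPM (UMIs of a gene scaled by the total of the sum), given as the mean ± SD over libraries, and a fold change is log2 with its standard error and adjusted p from edgeR. The design, the alternatives, 16 gene lists, 13 classes of cell type markers and the rule for named genes were set before the data were examined.

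In the first comparison DC0, DC1 and DC2 wells were summed together and set against fibroblast-named wells in the 6 libraries with at least 10 wells of each. The adjacent stages could not be fitted with at least 10 wells per sum. They were fitted with sums of at least 2 wells over libraries 1 to 8, with all 4 populations in the same model so that they share an estimate of the spread. That minimum of 2 and the comparison of DC2 with DC0 were chosen after seeing the data. The ninth library holds DC1 wells and no other population of cells, so it entered an alternative fit only.

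The fibroblast-named wells with at least 3000 UMIs (1155 of 1371) were clustered on a random part of their UMIs (binomial split with a probability of 0.5), and tests between clusters used the other part. Clustering took 2000 variable genes, leaving out cell cycle, stress, glycolysis, ribosomal and mitochondrial genes, 20 principal components, 15 neighbours and Leiden resolution 1.0. A cluster was called like a cell type when 3 or more of that type's markers lay at least 0.5 (log2) above the other wells with at least 10 CPM, 1 of them stood among the top 10 genes by fold (20 CPM added to both sides), and its leading genes did not go against the name. These limits and the 3000 UMI minimum were set after exploratory clusters had been seen. No doublet caller was run, because cells were sorted into separate wells. Whether wells with 2 cells account for a mixed cluster was tested from their UMI totals.

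The named genes of a comparison were those with adjusted p under 0.05, an absolute log2 fold change of at least 1, the same direction in every library, an average log2 CPM of at least 5 and no marker role: the 8 largest rises and the 8 largest falls. To these were added the 2 members of each gene list with the smallest p among those that passed, a fixed set of names and the markers. The lists were tested with camera (preset correlation 0.01) in limma, adjusted over the 16 lists, and again with an estimated correlation. The share of UMIs from cell cycle lists was compared by an exact, two-sided permutation test that flips signs over libraries. Shares of wells carry exact Clopper-Pearson 95% intervals. A fold against a group with 0 UMIs was computed from a floor of 3 UMIs over the group, and with 1 to 3 UMIs the ratio is given with its 95% counting interval. Intervals and floors cover counting error only, apart from intervals over a set of genes, which treat the genes as independent.

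Same-library sums deviated together: the correlation of their deviations from the population means was 0.105, 0.0816, 0.148, 0.223, 0.195 and 0.0900 in libraries 1 to 6, each above the highest value with any other library (0.0357, 0.0501, 0.121, 0.0247, 0.132 and 0.0895). The pairing itself comes from the design, since both populations of a library were sorted onto the same plate. The labels do not state whether libraries come from separate animals, so p-values measure the spread between libraries. Libraries 3, 5, 6 and 7 shared a sequencing run, 1 and 2 had runs of their own, and no run is given for 4, 8 and 9. Libraries 4 and 8 were counted as outside the shared run, though they may belong to it.

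Tested on simulated data with known changes, the first comparison recovered 56.6% of 2-fold and 91.8% of 4-fold changes among 9445 genes, with 1 false call in 146. DC0 against fibroblast recovered 91.9% and 100% among 1687 genes, with 6 false calls in 172. DC1 against DC0 recovered 54.5% and 95.7% (1741 genes, 8 false calls in 145), DC2 against DC1 67.9% and 100% (1651 genes, 8 in 147), DC2 against DC0 78.6% and 100% (1642 genes, 9 in 166), and the clusters 88.1% and 100% (4305 genes, 10 in 169).

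The alternatives tried were DESeq2, RLE size factors, no low-count filter, no replicate block, other minimum numbers of wells, every well thinned to 3000 UMIs, each library left out, and for the clusters all UMIs, a second seed, resolutions 0.6 and 1.5 and features without signalling genes. Added after seeing the data were recovered UMIs, wells with at least 1000 UMIs, sums of at least 20000 UMIs, the ninth library, libraries inside and outside the shared run, another naming limit, the 2 largest clusters, and the comparisons of the condensate-like cluster. Gene positions are from GENCODE vM21 (mm10), in which 265 of the 268 named genes had 1 annotated position.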

Results

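RNA of cells sorted from back skin of CD1 mouse embryos was counted at embryonic day 15, when dermal fibroblasts (Fb) gather into dermal condensates (DC), the clusters of cells that signal to the epidermis to build a hair follicle. The table held 1371 fibroblast-named wells, 149 DC0, 152 DC1 and 151 DC2 wells. The last 3 groups are called condensate cells here, in an order of stages taken from their numbers. DC0 may be a group before the condensate, since the bulk sample titles name pre-DC, DC1 and DC2, but the labels do not say so. The other wells were named for spike-ins. The labels do not state whether the 9 libraries come from separate animals, so p-values measure the spread between libraries.

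Libraries 1 to 7 held mostly fibroblasts, with 9 to 15 condensate wells in each. The eighth library held DC0 and DC2 wells and the ninth DC1 wells. The total was 4126636 UMIs in library 1, 2429401 in library 2, 6199057 in library 3, 3004449 in library 4 and 6414137 in library 5. Library 6 held 5898577 UMIs, library 7 3990703, library 8 2834557 and library 9 1436924. The median fibroblast well had 18509 UMIs, against 12773 for DC0, 10469 for DC1, 8333 for DC2 and 431 for the spike-in wells. In the 6 libraries that entered the first comparison, the sums ran from 56832 to 380695 UMIs for condensate cells and from 2372569 to 6033442 for fibroblasts.

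What separates condensate cells from the fibroblasts around them was the first question. Condensate cells had higher levels of signals such as Bmp7, Bmp4 and Fgf10, of the Notch ligand Dll1 and of the cell cycle inhibitor Cdkn1a. They had lower levels of Col1a1, Lox, Ogn and other matrix genes and of Mki67 and Pcna. In edgeR's quasi-likelihood test with the library as a block, 1007 genes were higher and 1269 lower of 9640 tested. The 3 libraries of the shared sequencing run gave 838 and 1072 on their own, and the 3 other libraries 373 and 662. Without the replicate block, 1138 genes were higher and 1285 lower.

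The fluorescent protein eGFP, carried as a row of the table, had the largest rise, 7.21 (SE 0.294, adjusted p = 6.92e-22, n = 6 libraries), from 1.66 ± 1.13 to 273 ± 63.7 CPM. Markers of the condensate fixed beforehand followed: Sox18, a transcription factor of dermal papilla cells (chromosome 2, 181669836 to 181671640, mm10), rose by 6.98 (SE 0.263), Sox2 by 6.63 (SE 0.426) and Foxd1 by 5.90 (SE 0.184, adjusted p = 1.43e-25). Cxcr4, the receptor of the chemokine Cxcl12, rose by 5.60 (SE 0.307). If the well names follow clusters made from the same cells, these genes were partly used to define the groups compared. The labels do not state the sort markers. If the sort used eGFP or another of these genes, the difference in that gene was set by the sort.

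Signals known to act between dermis and epidermis were among the largest rises. Bmp7 (chromosome 2, 172868012 to 172940321) rose by 3.93 (SE 0.185, adjusted p = 3.26e-20) to 465.8 ± 173 CPM from 26.2 ± 3.02, and Bmp4 by 3.45 (SE 0.177). Fgf10 rose by 3.26 (SE 0.170) and Edn3, a signal to pigment cell precursors, by 3.68 (SE 0.181). Rspo3, which strengthens WNT signalling, rose by 2.47 (SE 0.178), and Ndp, a ligand of the same receptors, by 6.88 (SE 0.541), from 9 UMIs in fibroblasts to 56. The matrix protein gene Smoc1, which binds BMPs (chromosome 12, 81026808 to 81186414), rose by 4.49 (SE 0.189, adjusted p = 1.36e-21), from 13.4 ± 3.46 to 318 ± 88.1 CPM. Glis1, a zinc finger factor, rose by 3.99 (SE 0.193). Sox11 and Trps1, transcription factors of mesenchyme, rose by 3.42 (SE 0.130) and 3.09 (SE 0.143).

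Heyl, a target of Notch (chromosome 4, 123233556 to 123249875), rose by 4.37 (SE 0.281, adjusted p = 5.75e-16), and the ligand Dll1 by 6.79 (SE 0.418), from 0.613 ± 0.450 to 82.7 ± 54.5 CPM. Of 10 Notch genes tested, 5 were higher and 0 lower, among them Hey1, Notch1 and Notch3 (members of lists named without values were picked after the results were seen). Adjusted over the list alone the numbers were the same, 5 and 0, and the median was 0.89 (camera, adjusted p = 0.000240, but adjusted p = 0.150 with an estimated correlation). Of 36 genes of the WNT list 14 were higher, Lef1 (2.31, SE 0.182) among them, and 8 lower, or 15 and 9 adjusted over the list alone (camera, adjusted p = 0.0204, but adjusted p = 0.103 with an estimated correlation). Inhibitors of WNT signalling went both ways: Wif1, Dkk1, Notum, Nkd1, Nkd2 and Kremen1 were higher, and Sfrp1 and Sfrp2 lower. Axin2, a common readout of WNT signalling, did not pass (0.31, adjusted p = 0.390). In the FGF list of 19 genes, 10 were higher and 3 lower, also adjusted over the list alone (camera, adjusted p = 0.00183, but adjusted p = 0.0756 with an estimated correlation).

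The hedgehog list went both ways. Gli1, a direct target of the pathway, rose by 2.25 (SE 0.154, adjusted p = 3.42e-15) to 336 ± 46.3 CPM from 65.0 ± 6.18, and the receptor Ptch1 by 2.88 (SE 0.440). Igf2, a growth factor carried on the same list, fell by 2.98 (SE 0.123). With 4 of 15 genes higher and 5 lower, also adjusted over the list alone, the list did not pass (camera, adjusted p = 0.647). The BMP list (5 of 20 higher, 6 lower) and the TGF-beta list (6 of 19 higher, 5 lower) did not pass either (0.662 and 0.647). Adjusted over the list alone they counted 5 and 6, and 7 and 6. Both had medians just below 0 (−0.03 and −0.01) while camera placed them on the higher side.

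Cdkn1a, an inhibitor of cyclin-dependent kinases (chromosome 17, 29090976 to 29100727), rose by 3.68 (SE 0.184, adjusted p = 2.03e-19), from 49.8 ± 17.7 to 697 ± 175 CPM. Plk2 rose by 3.84 (SE 0.241) and Btg1 by 1.16 (SE 0.130). Of 18 genes in the list of inhibitors, 9 were higher and 4 lower (Btg2, Cdkn2c, Gadd45b and Rbl1), also adjusted over the list alone (camera, adjusted p = 0.0126, but adjusted p = 0.103 with an estimated correlation). In the S phase list 18 of 42 genes were lower and 0 higher (24 and 0 adjusted over the list alone; median −0.61; camera, adjusted p = 2.20e-06, but adjusted p = 0.160 with an estimated correlation), with Pcna at −0.77 (SE 0.157). In the G2/M list 35 of 56 were lower and 0 higher (41 and 0 adjusted over the list alone; median −0.91; camera, adjusted p = 2.41e-08, but adjusted p = 0.432 with an estimated correlation). Mki67, a marker of dividing cells, fell by 1.26 (SE 0.260) and was lower in 5 of 6 libraries, and that call was lost without the replicate block. Top2a did not pass (−0.58, adjusted p = 0.0912).

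Of 45 matrix genes, 31 were lower and 7 higher (33 and 8 adjusted over the list alone; median −1.19; camera, adjusted p = 1.25e-09, but adjusted p = 0.0756 with an estimated correlation). Ogn, a small proteoglycan gene (chromosome 13, 49608046 to 49624501), fell by 4.89 (SE 0.321, adjusted p = 1.05e-15), with 8 UMIs in condensate cells. Lox, whose enzyme cross-links collagen, fell by 5.13 (SE 0.410; 5 UMIs), the secreted factor C1qtnf3 by 5.19 (SE 0.419; 4 UMIs) and Thbs2 by 4.29 (SE 0.231). Fndc1, named for its fibronectin domains, had 2 UMIs in condensate cells and was 34.4-fold lower there (95% counting interval 9.52 to 285). The fibroblast marker Col1a1 fell by 2.43 (SE 0.107), from 8875 ± 2387 to 1785 ± 548 CPM. The higher members included the basement membrane genes Col4a1, Col4a2 and Nid1.

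In the stress list 12 of 28 genes were lower and 1 higher (14 and 2 adjusted over the list alone; camera, adjusted p = 0.000357), and in glycolysis 7 of 19 were lower and 1 higher, also adjusted over the list alone (0.0204). With an estimated correlation the adjusted p was 0.0756 for stress and 0.103 for glycolysis, so that none of the list calls between condensate cells and fibroblasts held there. The lists of guidance genes (9 of 32 higher, 12 lower; 9 and 14 adjusted over the list alone), adhesion genes (4 of 23 higher, 6 lower; 4 and 8), transcription factors (15 of 48 higher, 16 lower; 16 and 16) and adipogenic genes (3 of 17 higher, 7 lower; 3 and 9) did not pass in camera, with adjusted p of 0.662, 0.825, 0.625 and 0.312. Nrp2, a receptor for guidance cues, rose by 3.10 (SE 0.139) and Cd44, an adhesion receptor, by 1.54 (SE 0.126).

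**Figure D1:**
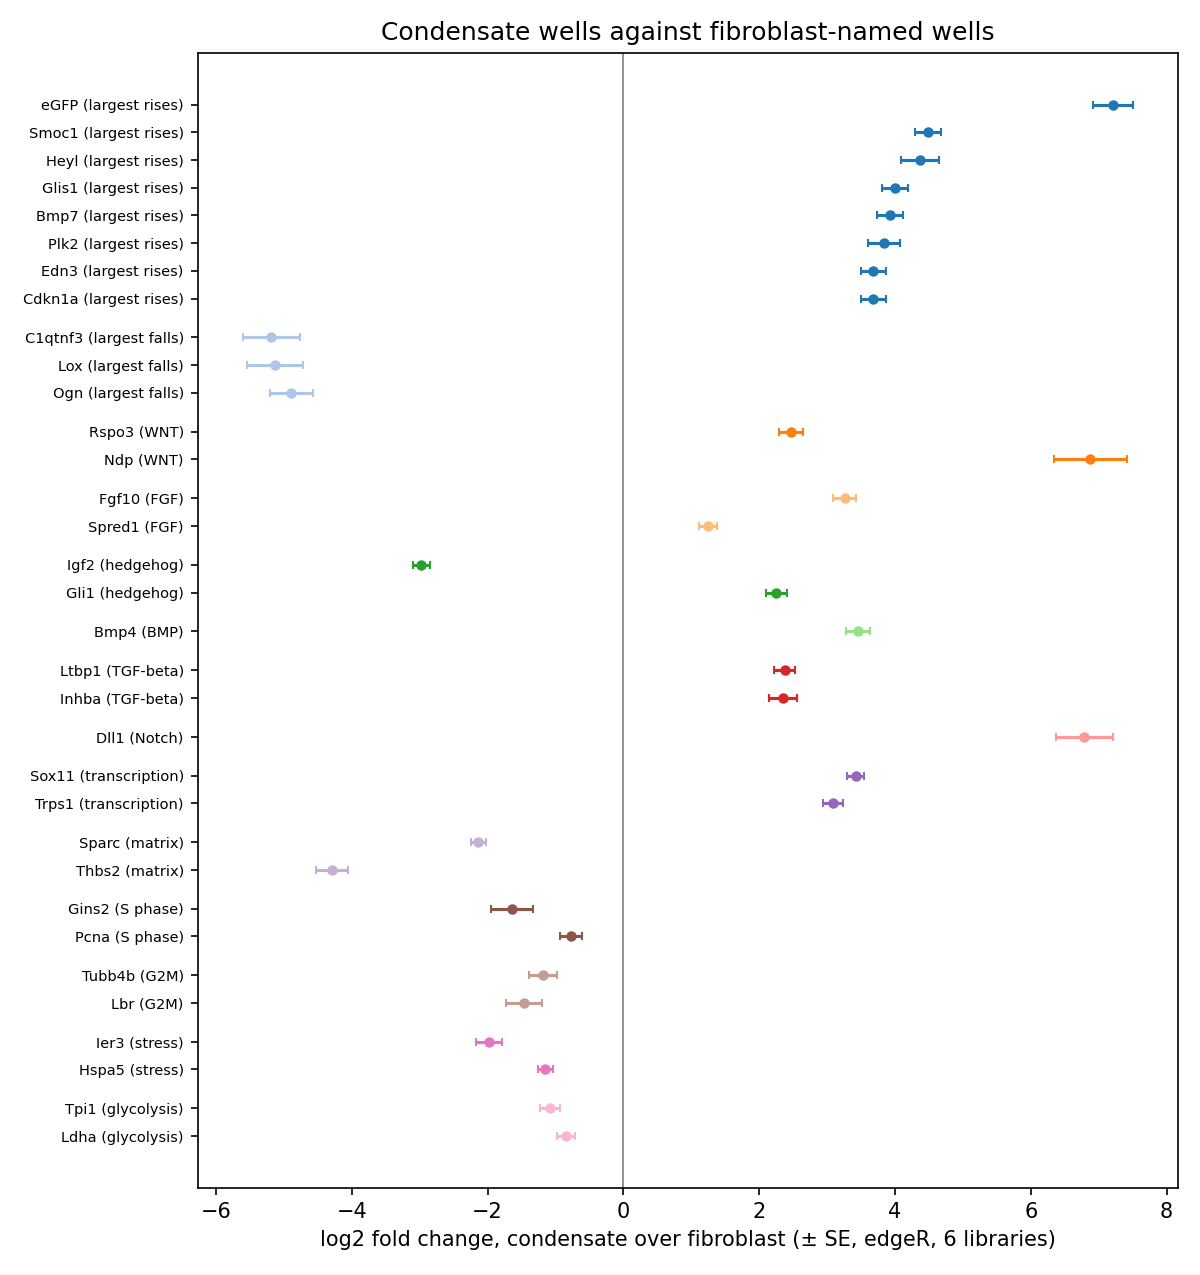
Log2 fold changes (± SE, x axis) of named genes between condensate wells and fibroblast-named wells over 6 libraries. The largest rise is eGFP at 7.21, and Lox and Ogn lie near −5.13 and −4.89.

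DC0 cells were set against fibroblasts to see what changes first in the order of stages. DC0 cells already had more Bmp4, Fgf10 and Gli1 and less of the matrix than fibroblasts. Dll1 passed too, but it was not higher in most libraries. The transcription factor Twist2 was also higher in DC0. Of 2069 genes tested with the library as a block, 243 were higher and 306 lower (edgeR, 7 libraries with both populations, in a fit over 8). The shared run alone gave 174 and 236, and the other libraries 99 and 108.

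In DC0, Twist2 (chromosome 1, 91801461 to 91848028) rose by 1.07 (SE 0.169, adjusted p = 5.07e-06), from 984 ± 80.0 to 2383 ± 950 CPM. Gli1 rose by 2.30 (SE 0.197), Bmp4 by 3.44 (SE 0.352), Fgf10 by 3.28 (SE 0.243) and Lef1 by 2.53 (SE 0.253). The Notch ligand Dll1 rose by 4.13 (SE 0.721) and was higher in 2 of 7 libraries. It had 4 UMIs in the DC0 wells of libraries 1 to 7 and 50 (33.9 CPM) in those of library 8. Heyl rose by 3.31 (SE 0.513, higher in 4 of 7). The cell cycle gene Ccnd1 rose by 1.56 (SE 0.213) together with Cdkn1a (4.06, SE 0.3998, higher in 6 of 7 libraries). Dclk1, a kinase of neurons, reached 803 ± 431 CPM from 62.9 ± 7.53 (3.38, SE 0.251, adjusted p = 6.94e-13). Agtr2, the angiotensin receptor of embryonic mesenchyme, fell by 3.86 (SE 0.388, adjusted p = 7.77e-10), from 1053 ± 194 to 75.0 ± 69.5 CPM, and the chemokine gene Cxcl12 fell by 3.74 (SE 0.444). Over libraries 1 to 7 Lox had 0 UMIs in DC0 and was at least 23.2-fold lower. The DC0 wells of library 8 held 7 UMIs of Lox (4.74 CPM). Cdkn1c (0.83, adjusted p = 0.172), Mki67 (−0.84, adjusted p = 0.282) and Crabp1 (0.55, adjusted p = 0.232) did not pass.

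Between DC0 and fibroblasts, 25 of 37 matrix genes were lower and 5 higher (25 and 6 adjusted over the list alone; median −1.34; camera, adjusted p = 3.05e-07), and this call held with an estimated correlation (adjusted p = 0.00544). Lists of FGF (0.00399), WNT (0.00829), inhibitors (0.0246), Notch (0.0265) and transcription factors (0.0336) passed on the higher side by camera's adjusted p, and stress (0.0139) and G2/M (0.0373) on the lower side. Those calls were lost with an estimated correlation, with adjusted p of 0.0834 for FGF, WNT and transcription factors, 0.138 for inhibitors and Notch, 0.143 for stress and 0.628 for G2/M. Notch (0.0593) and transcription factors (0.101) were also lost without the replicate block.

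Few genes passed between DC0 and DC1, a comparison that recovered 54.5% of simulated 2-fold changes. DC1 cells had more of the chemokine receptor Cxcr4, of the activin subunit Inhba and of Frzb and Fzd2, which bind WNTs. In edgeR, 20 genes were higher and 4 lower, with 202 at unadjusted p under 0.05. The fit held 8 libraries, of which 7 had both populations. Only 1 and 1 passed within the shared run and 3 and 0 in the other libraries. Leaving out library 5 gave 0 lower genes and leaving out library 7 gave 8.

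Cxcr4 rose by 2.69 between DC0 and DC1 in edgeR (SE 0.567, adjusted p = 0.00693). It averaged 5.81 ± 10.3 CPM in DC0 and 155.5 ± 110 CPM in DC1 over libraries 1 to 7, and was higher in DC1 in all 7. These means give a larger fold than the fit, which also used library 8, where DC0 wells had 58.3 CPM. Frzb, a secreted WNT antagonist (chromosome 2, 80411970 to 80447625), rose by 2.67 (SE 0.477, adjusted p = 0.00227) and the WNT receptor Fzd2 by 1.28 (SE 0.223). Inhba (chromosome 13, 16011851 to 16031621) rose by 2.54 (SE 0.483, higher in 5 of 7 libraries), Nrp2 by 1.45 (SE 0.275), and Pdlim3, an actin-binding protein of muscle, by 2.86 (SE 0.567). Adamts15, a protease of the matrix, had 55 UMIs in DC1 and 2 in DC0 over libraries 1 to 7. The ratio of these UMIs, scaled by the totals, was 25.2 (95% counting interval 6.64 to 213). The fit, which also used library 8, gave a smaller log2 fold change of 3.15 (SE 0.574). Twist2 fell by 0.72 (SE 0.179, adjusted p = 0.0269), a call lost when any of libraries 1, 2, 4, 5 or 6 was left out. The calls of Cxcr4, Fzd2, Nrp2 and Twist2 were lost with at least 5 cells per sum and both inside and outside the shared run. Pdlim3 was lost inside and outside it, Inhba and Frzb inside it, and Adamts15 outside it and with at least 5 cells. Nrp2 and Twist2 were lost with every well thinned to 3000 UMIs, and Twist2 with no filter. Cdkn1a (−0.82, adjusted p = 0.526), Ccnd1 (−0.56, adjusted p = 0.343) and Trps1 (−0.01) did not pass, and no gene list did.

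From DC1 to DC2, Notch targets rose, and Twist2, the upper dermal marker Crabp1 and the cell cycle gene Ccnd1 fell. Of the 2069 genes, 24 were higher and 27 lower in edgeR (7 libraries with both populations, in a fit over 8). The share of higher genes depended on the scaling: it was 47.1% with TMM, 65.2% with RLE and 57.1% with DESeq2. Within the shared run 11 were higher and 5 lower. The other libraries gave 0 and 0 in edgeR, with 99 at unadjusted p under 0.05. Without the replicate block 37 were higher and 27 lower. Leaving out library 3 gave 9 and 9.

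Hey1, a Notch target (chromosome 3, 8663359 to 8667256), rose by 2.36 between DC1 and DC2 (SE 0.424, adjusted p = 0.00125), from 49.4 ± 32.4 to 211 ± 110 CPM, and Heyl rose by 1.96 (SE 0.470) to 499 ± 272 CPM. The call of Heyl was lost with DESeq2, without library 3, 4 or 6, and both inside and outside the shared run, and that of Hey1 with at least 5 cells per sum. Of 6 Notch genes, 3 were higher and 0 lower (4 and 0 adjusted over the list alone; median 1.51; camera, adjusted p = 1.50e-06), and this held with an estimated correlation (adjusted p = 0.00696). Inhba rose by 1.93 (SE 0.339) and the netrin receptor Unc5b by 2.45 (SE 0.412, adjusted p = 0.000649). Twist2 fell by 1.78 (SE 0.209, adjusted p = 1.17e-06), from 1332 ± 268.2 to 382.2 ± 133.02 CPM. Crabp1, which binds retinoic acid, fell by 2.04 (SE 0.417), Cyp26b1, which breaks it down, by 1.22 (SE 0.269), and Ccnd1 by 1.45 (SE 0.268, adjusted p = 0.00163). The replication gene Mcm3 fell by 2.26 (SE 0.522). Outside the shared run the calls of Twist2, Crabp1, Cyp26b1 and Ccnd1 were lost, and inside it those of Cyp26b1 and Ccnd1, which were also lost with every well thinned to 3000 UMIs. That of Cyp26b1 was lost without library 3 or 4 too. With at least 5 cells per sum those of Unc5b and Mcm3 were lost.

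Few members of the other lists passed between DC1 and DC2. In the S phase list 1 of 10 genes was lower and 0 higher (7 and 0 adjusted over the list alone; camera on the lower side, adjusted p = 0.000456, but adjusted p = 0.278 with an estimated correlation). In the G2/M list 1 of 24 was lower and 0 higher, also adjusted over the list alone (camera on the lower side, adjusted p = 0.000101, but adjusted p = 0.388 with an estimated correlation). In the matrix list 1 of 37 was higher and 1 lower (median 0.09; camera on the higher side, adjusted p = 0.0165). That call was lost without the replicate block (adjusted p = 0.0902) and with an estimated correlation (adjusted p = 0.278).

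DC2 was also set against DC0, the ends of the order, after the adjacent steps had been seen. DC2 cells had more Notch ligand and targets, activin and apolipoprotein, and less Twist2, Crabp1 and Mcm3. In edgeR 174 genes were higher and 190 lower over 8 libraries. The shared run gave 85 and 65, and the other libraries 31 and 17. The share of higher genes was 47.8% with TMM, 59.9% with RLE and 69.4% with DESeq2, and leaving out library 8 gave 101 higher and 99 lower.

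Inhba rose by 4.47 between DC0 and DC2 (SE 0.385, adjusted p = 1.24e-10), from 21.4 ± 15.4 to 391 ± 230 CPM. Dll1, the Notch ligand (chromosome 17, 15367354 to 15376872), rose by 3.92 (SE 0.495), Hey1 by 2.80 (SE 0.382) and Cxcr4 by 3.95 (SE 0.458, adjusted p = 9.10e-08). Of 6 Notch genes, 4 were higher and 0 lower (5 and 0 adjusted over the list alone; median 2.37; camera, adjusted p = 8.86e-07), which held with an estimated correlation (adjusted p = 0.00507). Apod, a lipid carrier (chromosome 16, 31296192 to 31314808), rose by 3.42 (SE 0.563) and Frzb by 2.84 (SE 0.422). Rspo3 rose by 2.52 (SE 0.357). Twist2 fell by 2.50 (SE 0.196, adjusted p = 2.76e-11), Crabp1 fell by 3.36 (SE 0.383, adjusted p = 7.82e-08) and Ccnd1 fell by 2.02 (SE 0.244, adjusted p = 2.33e-07).

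Mcm3, a replication gene, fell by 2.93 between DC0 and DC2 (SE 0.424) and Pcna fell by 1.70 (SE 0.337), with 8 of 10 S phase genes lower and 0 higher (10 and 0 adjusted over the list alone; camera, adjusted p = 3.50e-05, but adjusted p = 0.3001 with an estimated correlation). In the G2/M list 4 of 24 were lower and 0 higher (6 and 0 adjusted over the list alone; 0.000346), and in glycolysis 3 of 10 lower and 0 higher (4 and 0 adjusted over the list alone; 0.0283). With an estimated correlation the adjusted p was 0.491 for G2/M and 0.3001 for glycolysis. Cdkn1c fell by 2.14 (SE 0.504, adjusted p = 0.00283), although it was lower in only 5 of 8 libraries and in library 8 it went the other way, with 2822 CPM in DC2 and 1819 in DC0. The call was lost outside the shared run. Gli1 (0.12, adjusted p = 0.747), Trps1 (0.06, adjusted p = 0.882), Lef1 (−0.63, adjusted p = 0.100) and Sox2 (0.50, adjusted p = 0.482) did not pass between DC2 and DC0.

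**Figure D2:**
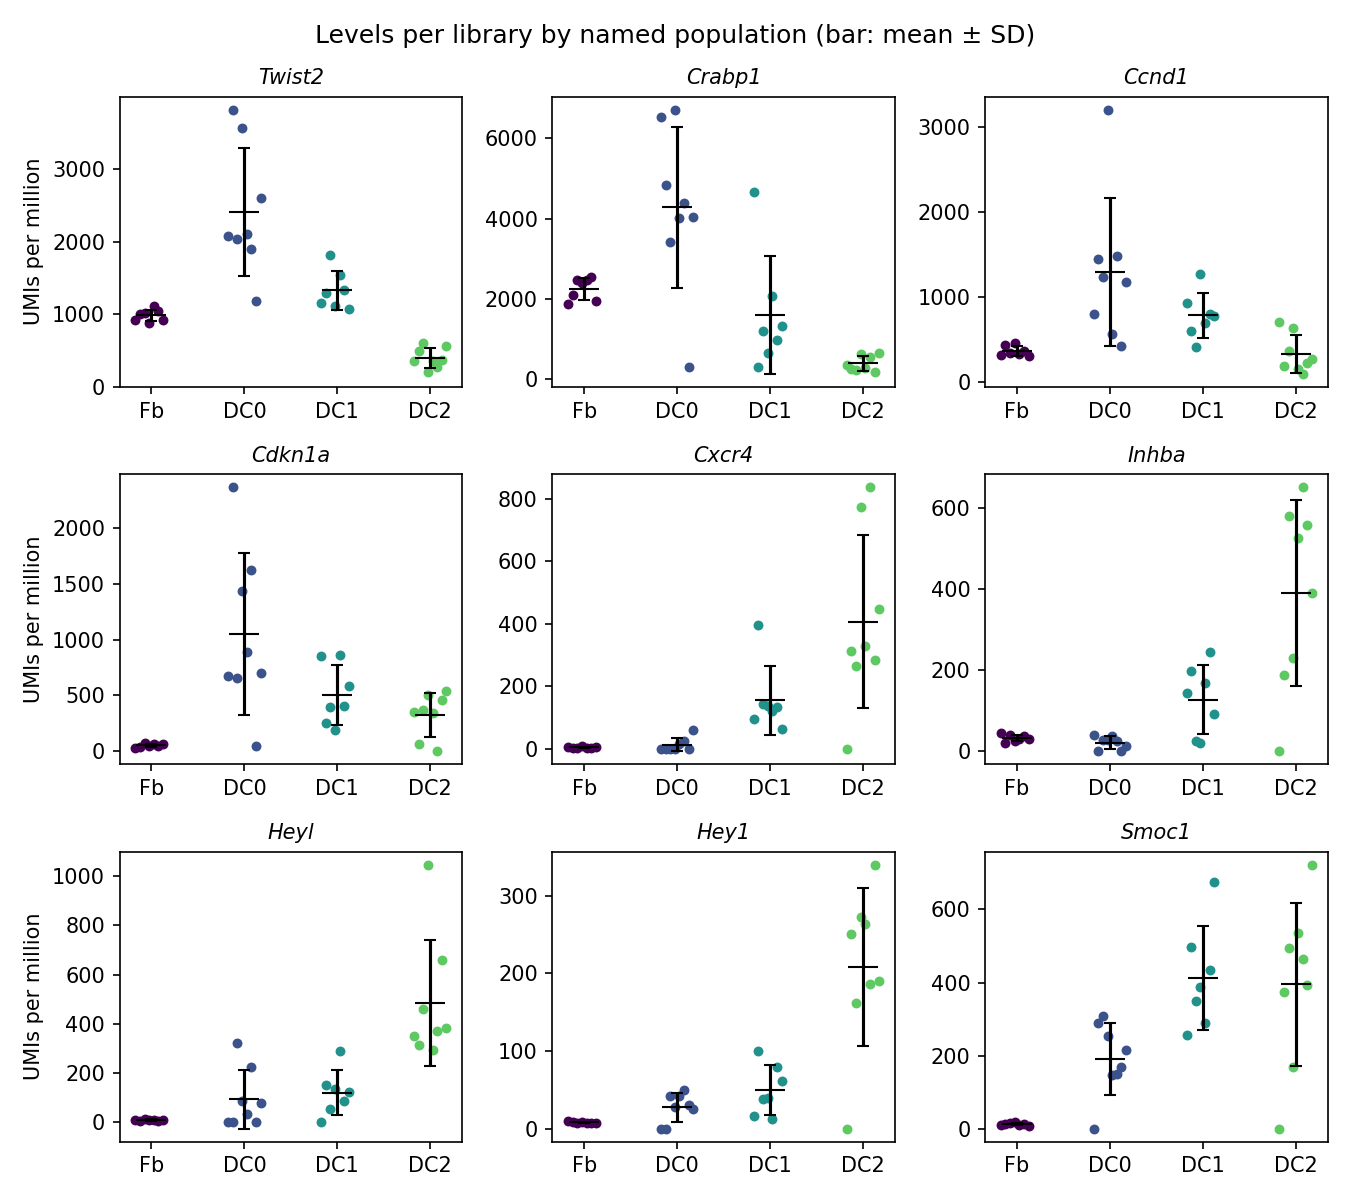
Level (CPM, y axis) of 9 genes in each library's fibroblast, DC0, DC1 and DC2 wells, with bars for the mean ± SD. Twist2 averages 984, 2410, 1332 and 404 CPM in that order, and Inhba 32.6, 21.4, 128 and 391 CPM.

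Whether condensate cells divide less was also asked of the share of all UMIs that comes from cell cycle genes. Condensate cells spent a smaller share on S phase genes than fibroblasts of the same library, 0.259% ± 0.0800 against 0.394% ± 0.0167 (SD, n = 6), and lay lower in 6 of 6 libraries. The exact two-sided permutation test gave p = 0.03125, the smallest that 6 libraries allow, and 0.125 after adjustment over 12 such tests, so that no share passed after adjustment. For G2/M genes the shares were 0.443% ± 0.350 and 0.768% ± 0.0670, lower in 5 of 6 libraries with library 5 as the exception (exact p = 0.125, adjusted 0.25). DC2 had 0.154% ± 0.0391 in S phase genes against 0.276% ± 0.174 in DC1 (lower in 6 of 7; exact p = 0.03125, adjusted 0.125). DC2 also lay below DC0, at 0.150% ± 0.0380 against 0.321% ± 0.197 (lower in 6 of 8; exact p = 0.046875, adjusted 0.141). DC0 against fibroblasts did not pass (exact p = 0.375).

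**Figure D3:**
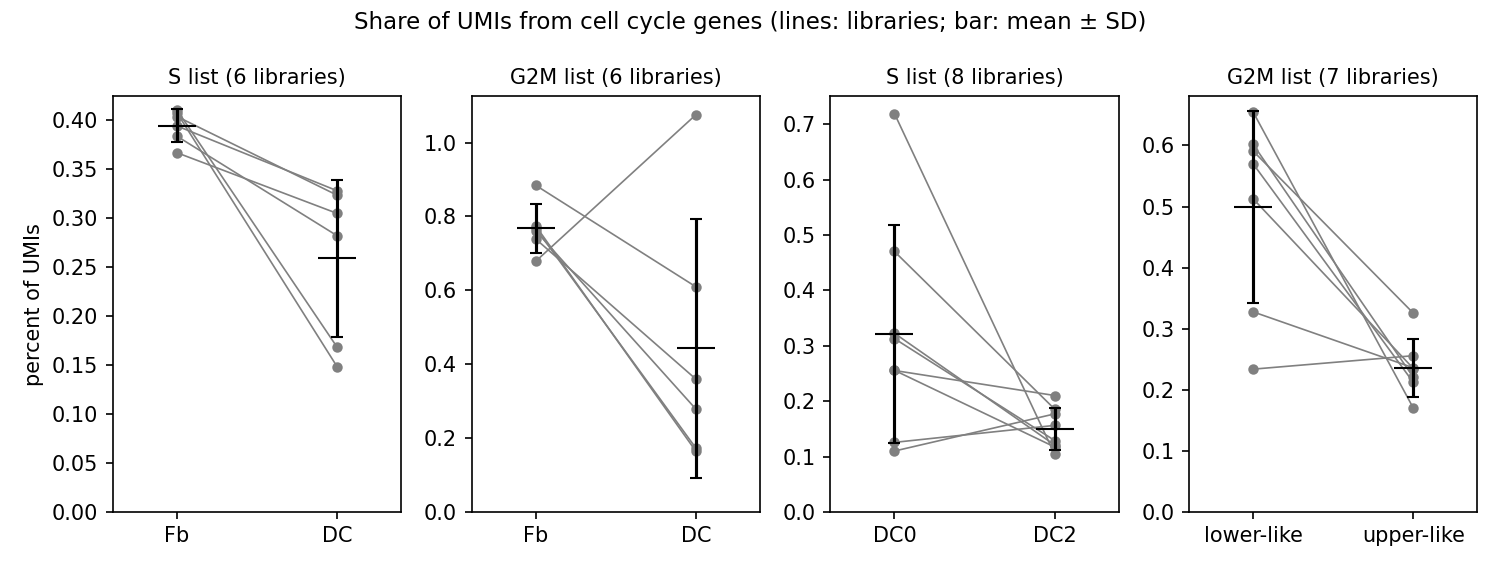
Percent of UMIs from cell cycle genes (y axis) in paired groups of cells, with a line for each library. Condensate cells lie below fibroblasts in 6 of 6 libraries for S phase genes.

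The fibroblast-named wells were clustered to see which kinds of fibroblast they held. Of 10 clusters of 1155 wells, 3 were named here. An upper-like cluster had 190 wells (16.5%, 95% interval 14.4 to 18.7), a lower-like cluster fewer (10.7%, 9.01 to 12.7) and a condensate-like cluster 57 (4.94%, 3.76 to 6.35). The last had 6 condensate markers raised on the UMIs used for clustering. On the other UMIs, Sox2 was at 0.0 CPM there, Bmp3 at 1.82, Cxcr4 at 5.45 and Gal at 5.45. The condensate-like share depended on the clustering resolution: it was 0 at 0.6, where no such cluster was found, and 1.56% at 1.5. The other 7 were left unnamed, 703 wells (60.9%) in 6 of them and 81 in another. The naming rule called that cluster of 81 wells melanoblast. The name was not kept, since the UMIs of the melanoblast genes that led it came mostly from 1 well each. By library, the upper-like share ran from 13.5% to 21.3%, the lower-like share from 7.43% to 13.2% and the condensate-like share from 2.78% to 7.69%. With a naming limit of log2 1.0 in place of 0.5 the upper-like cluster lost its name and the other names stayed. The sort and the choice of wells can set such shares.

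Upper-like and lower-like fibroblasts were compared because papillary and reticular dermis descend from such layers. Upper-like cells had more Runx1, Runx3 and Lef1. Lower-like cells had more of most matrix genes tested and more Sfrp1 and Sfrp2. On the UMIs kept from clustering, 862 of 4551 genes were higher and 957 lower in edgeR with the library as a block (7 libraries). The shared run gave 753 and 892, and the other libraries 457 and 527. Genes used for clustering were 18.1% of the higher and 22.7% of the lower, against 10.7% of all tested. A pair of upper markers went against the name: Dkk2 was lower in the upper-like cluster (−4.52), and Tnmd, with 0 UMIs there, was at least 6.36-fold lower.

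Runx3 (chromosome 4, 135120652 to 135177990) was 109-fold higher in the upper-like cluster (95% counting interval 29.6 to 906; 2 UMIs in the lower-like cluster), and Runx1 was higher by 5.87 (SE 0.358, adjusted p = 1.62e-17). Lef1, a transcription factor of the WNT pathway, was higher by 4.53 (SE 0.281, adjusted p = 2.90e-17), Axin2 by 1.42 (SE 0.251) and Twist2 by 1.67 (SE 0.0946). Lower in the upper-like cluster were the WNT inhibitors Sfrp2 (−5.27, SE 0.149, adjusted p = 6.63e-29) and Sfrp1 (−4.57, SE 0.185), while the inhibitor Wif1 was higher (4.17, SE 0.225). The transcription factors Tcf7l1 and Tcf7l2 were lower. Of 24 WNT genes 12 were higher and 10 lower, also adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.478). Cdkn1c fell from 5129 ± 898 to 408 ± 132 CPM (−3.79, SE 0.0861), and the matrix gene Aspn from 847 ± 123.9 to 11.2 ± 5.39 CPM (−6.46, SE 0.179). Fmod, a collagen-binding proteoglycan gene (chromosome 1, 134037254 to 134048277), had 0 UMIs in upper-like cells and was at least 54.2-fold lower.

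In the upper-like cluster 32 of 42 matrix genes were lower and 4 higher (33 and 4 adjusted over the list alone; median −1.31; camera, adjusted p = 1.21e-17), which held with an estimated correlation (adjusted p = 0.0316). In the G2/M list 21 of 28 genes were lower and 0 higher (22 and 0 adjusted over the list alone; camera, adjusted p = 5.08e-06), Top2a (−2.22, SE 0.194) and Mki67 (−2.04, SE 0.211) among them, but with an estimated correlation the adjusted p was 0.412. Stress genes were lower (15 of 22, with 3 higher; 0.000160, or 0.291 with an estimated correlation). The share of UMIs from G2/M genes was 0.236% ± 0.0476 in upper-like and 0.499% ± 0.157 in lower-like cells (lower in 6 of 7 libraries; exact two-sided permutation p = 0.03125, adjusted 0.125). Some unnamed clusters had cell cycle genes among their leading genes, such as Rrm2 and E2f7 in a cluster of 112 wells and Cenpf and Cdc20 in that of 81, and these 2 held Crabp1 at 3354 and 3422 CPM, against 3965 in the upper-like cluster. Wells in cycle with upper markers thus lay outside the upper-like cluster, and its lower G2/M values depend on how the wells were divided among clusters.

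The condensate-like cluster, compared after it had been seen, held fibroblast-named wells with part of the DC0 profile. Its cells had the hedgehog target and Twist2 at the level of DC0, less of the signals Bmp4 and Fgf10, and more collagen. Against the other clustered fibroblasts, 174 genes were higher and 279 lower of 2018 (edgeR, 7 libraries), and against DC0 25 were higher and 28 lower. Levels given against DC0 leave out library 1, which had fewer than 2 DC0 wells of at least 3000 UMIs. Gli1 rose by 2.34 against other fibroblasts (SE 0.187, adjusted p = 8.14e-11), from 55.2 ± 6.79 to 291 ± 38.3 CPM, Twist2 by 1.17 (SE 0.140) and Trps1 by 2.72 (SE 0.226). Against DC0, Gli1 (−0.00) and Twist2 (−0.07) did not pass. Cdkn1c fell by 2.50 (SE 0.287, adjusted p = 1.64e-06), from 4843 ± 2069 to 858 ± 603 CPM, Fgf10 by 1.58 (SE 0.309) and Bmp4 by 1.51 (SE 0.364), while Col1a1 rose by 1.13 (SE 0.128). The 243 genes higher in DC0 made up a median of 5.50% of the UMIs of a well in this cluster, 3.34% in other fibroblasts and 9.02% in DC0.

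**Figure D4:**
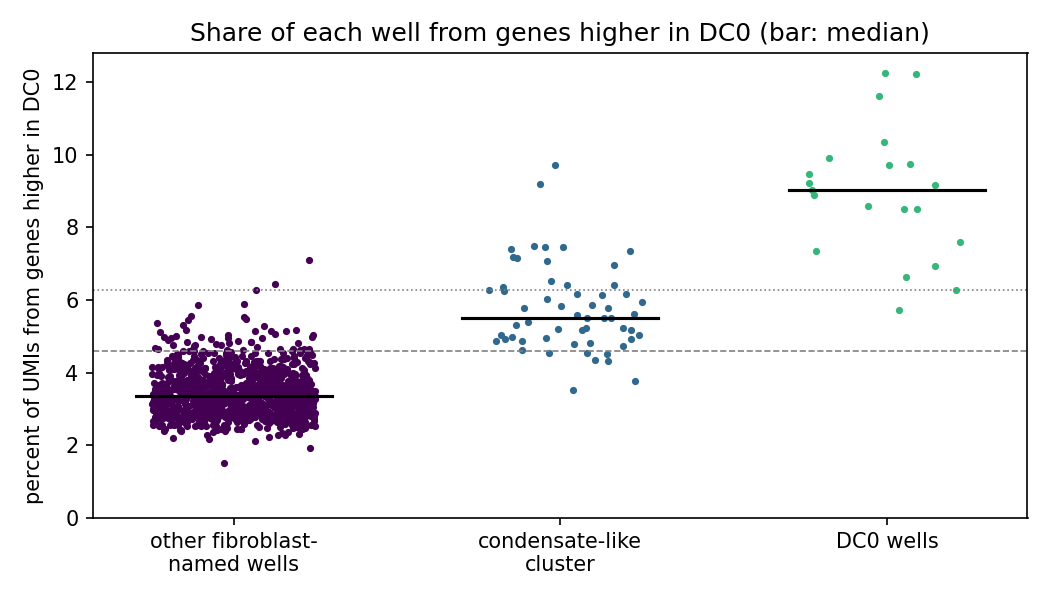
Percent of UMIs from the 243 genes higher in DC0 (y axis) in each other fibroblast-named, condensate-like and DC0 well, with bars for the median. The condensate-like wells have a median of 5.50%, between 3.34% and 9.02%, and 34 of 57 lie between the dashed line at 4.58% and the dotted line at 6.26%.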

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

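The tests of 2 cells in a well, of spilled RNA and of swapped labels were chosen after the results they bear on were seen; those of misnamed wells and of the eighth library were written before.

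In 6 of 46 groups of values a library stood apart from the others of its group, where chance gives about 1 in 20 groups. The level of eGFP in condensate cells was 399 CPM in library 1 and 228.6 to 263.3 CPM in the other 5. Plk2 reached 505 CPM in the condensate cells of library 4 (81.4 to 194 in the others) and 25.8 CPM in its fibroblasts (5.56 to 11.4 in the others). Among genes that were scarce in condensate cells, Csf1 was found in library 3 alone (1 UMI, 3.76 CPM) and Glt8d2 in library 5 alone (2 UMIs, 5.25 CPM). Lox, with 5 UMIs in all, lay at 35.2 CPM in library 2, against 0 to 11.1 CPM in the others. With so few UMIs a library that holds 1 stands apart readily, so the tally of 6 is not to be set against the chance rate.

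Signals also appeared in wells outside the main comparisons. Wells named for spike-ins held 287 UMIs of the collagen gene Col1a1, 80 of the keratin gene Krt5 and 28 of Krt14. In the ninth library, named for DC1 cells only, there were 249 UMIs of the Schwann cell gene Sox10 and 314 of Krt5.

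The first weighed pattern was the cluster of 57 fibroblast-named wells with genes of DC0. DC0 wells given the wrong name would lie at the level of DC0. Of the 57 wells, 34 (59.6%) lay between the other fibroblasts and DC0, and 16 at or above the 5th percentile of DC0. That percentile came from 21 DC0 wells, and the 243 genes were picked with the same wells. The choice of genes can raise these DC0 wells above misnamed ones, so the test cannot exclude misnaming. Wells with 2 cells would hold more UMIs than others, and the median ratio was 0.808 (0.673 to 1.06 over libraries). That argues against 2 cells in most wells of the cluster. A smaller number of such wells could leave the medians unchanged and is not excluded. RNA spilled from condensate wells would carry eGFP, Sox2 and Sox18 in proportion. These genes, with 30 UMIs in the cluster, reached 10.9% (7.21 to 15.8) of the way to DC0. The median gene reached 40.5% (36.2 to 45.5). That interval came from resampling the 243 genes 1000 times, so it treats genes as independent. The interval for eGFP, Sox2 and Sox18 covers counting error. If the well names follow clusters of these cells, wells high in eGFP, Sox2 and Sox18 would tend not to be named fibroblast. The test then cannot exclude spilled RNA. An open alternative is that the well names divide a continuum from fibroblast to DC0, so that these wells may be fibroblasts on the way to DC0, which no test here addressed.

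The second pattern was the number of genes past the threshold in each comparison, set against chance. With labels swapped within libraries, condensate against fibroblast reached at most 69 genes in the other of 32 splits, against 2276. DC0 against fibroblast reached at most 302 in 64 splits (549 with the real labels), DC1 against DC0 9 (24), DC2 against DC1 35 (51) and the upper-like against the lower-like cluster 0 (1819). In 100 splits drawn for DC2 against DC0 the highest other count was 274, against 364. In each comparison only 1 split, the real one, gave as many genes, which makes chance unlikely between the named populations. That does not hold if the names were made from these cells' expression, an origin the labels do not state. The 2 clusters were made from these cells, so swapping their labels was bound to give fewer genes and decides nothing.

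The third pattern was the weight of the eighth library, by far the deepest source of DC0 and DC2 cells. Without it, 200 genes passed between DC2 and DC0, and 99.0% of them (96.4 to 99.9, genes taken as independent) had the same direction in that library alone. The prediction, set beforehand, that an effect of the plate would give no more than 50% was wrong, since DC0 and DC2 share that plate and genes called without it cannot owe their call to it. Whether the further genes called with it depend on that plate stays open.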

How the results depend on the processing

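Chosen after seeing the data were the comparison of DC2 with DC0, the libraries inside and outside the shared run, recovered UMIs, wells with at least 1000 UMIs, sums of at least 20000 UMIs, the ninth library and the 2 largest clusters. Of 6884 pairs of a named gene and an alternative, 6478 kept direction and side of the threshold, 368 fell short of it, 33 newly passed and 5 reversed. In another 99 pairs, which passed neither in the main fit nor in the alternative, the sign changed. The cause of a change was not tested unless stated.

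Thinning every well to 3000 UMIs also left 4 of 6 libraries for condensate against fibroblast and 6 of 7 for the clusters, and fewer genes were tested. The counts were lower: 252 higher and 368 lower genes for condensate against fibroblast, 51 and 37 for DC0 against fibroblast, 2 and 0 for DC1 against DC0, 3 and 2 for DC2 against DC1, 47 and 24 for DC2 against DC0, and 226 and 258 for the upper-like against the lower-like cluster. Outside the shared run the counts were 373 and 662, 99 and 108, 3 and 0, 0 and 0 (99 at unadjusted p under 0.05 in edgeR), 31 and 17, and 457 and 527 in the same order. Libraries 4 and 8, whose run is not given, were counted as outside the shared run. Inside it, DC1 against DC0 gave 1 and 1, DC2 against DC1 11 and 5, and DC2 against DC0 85 and 65.

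DESeq2, which tested more genes, gave 462 higher genes for DC0 against fibroblast, 40 for DC2 against DC1 and 342 for DC2 against DC0. RLE scaling gave 16 lower for DC2 against DC1. With no filter there were 1257 lower genes for DC0 against fibroblast, 45 higher for DC1 against DC0, 79 lower for DC2 against DC1, 389 higher and 355 lower for DC2 against DC0, and 1557 lower in the upper-like cluster. With at least 5 cells per sum, DC1 against DC0 gave 9 and 2, DC2 against DC1 13 higher, and DC2 against DC0 368 and 436. With the ninth library added and the block removed at once, DC1 against DC0 gave 44 and 15.

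Without the replicate block DC2 against DC1 gave 37 higher genes, and glycolysis no longer passed between condensate cells and fibroblasts (0.0513). The Notch (0.0593) and transcription factor (0.101) lists for DC0 against fibroblast and the matrix list for DC2 against DC1 (0.0902) were lost too. Named genes that lost their call without the block were Cdkn1c, Mki67 and Id1 (condensate against fibroblast), Ube2c and Cks2 (DC0 against fibroblast), Smoc1 and Crabp1 (DC1 against DC0), Hmgb2 (DC2 against DC1), and Thy1, Col3a1 and Dcn (DC2 against DC0). The block changed no other named call.

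With each library left out in turn, the lower genes of DC1 against DC0 ran from 0 to 8 (0 without library 5, 8 without 7, 7 without 8). DC2 against DC1 ran from 9 to 28 higher (9 without library 3, 12 without 4 or 5, 15 without 7, 14 without 8) and from 9 to 31 lower (9 without 3, 13 without 4, 16 without 5, 12 without 6, 10 without 8). DC2 against DC0 ran from 101 to 196 higher (101 without library 8) and 99 to 217 lower (105 without 5, 99 without 8). The S phase share kept its direction, but 5 libraries cannot give an exact permutation p below 0.0625, nor the 4 thinned ones below 0.125.

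With an estimated correlation, which widens the test, the lists between condensate cells and fibroblasts had adjusted p of 0.160 (S phase), 0.432 (G2/M), 0.103 (inhibitors, WNT and glycolysis), 0.0756 (FGF, matrix and stress) and 0.150 (Notch).

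On all UMIs the upper-like against lower-like counts were 1326 and 1452, of 7005 genes tested in place of 4551. The 2 largest clusters gave 335 and 342, and there Mcm3 (−0.13), Top2a, Flrt2 (0.0123), Thy1 (−0.33) and Ldha (−0.35) reversed, with the upper-like cluster kept and another cluster in place of the lower-like one (upper vs lower: Top2a log2 fold change 0.00642). The upper-like share was 19.7% with a second seed, 19.8% at resolution 0.6 and 22.8% at 1.5. The condensate-like share was 0 at resolution 0.6 (no such cluster), 1.56% at 1.5 and 3.55% without signalling genes.

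Settings of the clustering were not run for comparisons of named populations, which use no clusters. A minimum of 20 cells left no library for condensate against fibroblast or the cell cycle shares and could not be fitted for the stages. The smallest DC2 sum, in library 1, held 2855 UMIs.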

Other observations

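No hypothesis was tested in this part, and these values were picked after they were seen.

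The eighth and ninth libraries, which hold condensate wells only, had Twist2 at 2600 CPM in DC0, 1076 in DC1 and 557 in DC2, and Crabp1 at 4050, 1046 and 650. Inhba stood at 13.6, 165 and 391 CPM in the same order, Heyl at 78.6, 246 and 384.05, and Cxcr4 at 58.3, 214.3 and 447.

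Markers of other cell types in condensate wells differed from library to library. Sox10, which marks Schwann cells and pigment cell precursors, stood at 173 CPM in the ninth library, 76.9 in the eighth and 4.67 to 33.2 in the condensate wells of libraries 1 to 7, against 13.9 in fibroblasts. Krt5, a keratinocyte gene, stood at 218.5 CPM in the ninth library, 4.94 in the eighth and 7.42 to 195.98 in the condensate wells of libraries 1 to 7, against 82.7 in fibroblasts.

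Over the 1155 clustered wells, the well richest in each gene held 683 of 841 UMIs of Dct and 478 of 595 of Pmel, melanoblast genes that led the cluster of 81 wells left unnamed. For the mast cell gene Cpa3, which led another unnamed cluster, it held 859 of 2757 UMIs.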
